A study of Arabidopsis thaliana with 8 samples.

How the data were processed

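Total RNA of whole Arabidopsis seedlings was hybridised to Affymetrix arrays, 1 sample per array. The 4 groups were wild type (ecotype Col-1) and the TabZIP6-overexpressing line L20, each before cold at 22 °C and after 6 h at 4 °C, with 2 arrays per group. Groups and replicate numbers came from the sample titles, and every one of the 8 value columns matched 1 sample. The labels state that biotinylated cRNA was made from 6 ug of total RNA.

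The authors deposited 1 table with 22810 probe sets and 8 arrays on the log2 scale. RMA, which corrects the background, normalizes arrays to a shared distribution and summarises the probes of a probe set, is named by the submitters' processing notes; its version, and whether all 8 arrays were processed together, is not given in the sources used here. The array medians of the deposited log2 values were 4.95, 5.05, 5.06, 5.03, 5.00, 5.05, 5.01 and 5.04, in the order wild type before cold, L20 before cold, wild type after cold and L20 after cold with replicate 1 first. The medians were close to each other and not identical. The upper quartiles differed more, from 6.28 in replicate 1 of wild type before cold to 6.65 in replicate 1 of L20 before cold. No scanner files were used here, so background levels per probe were not analysed. There were 0 missing values. A normalization to a shared distribution removes any change that affects most genes alike, so changes are relative to the bulk of the genes.

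The 64 control probe sets were left out of all tests, which left 22746. Gene names came from the platform annotation provided with the value table, updated through Entrez identifiers with RefSeq gene names of assembly TAIR10.1. Of the tested probe sets, 13513 had 1 gene, 503 had several and 8730 had none there; 13436 of those with 1 gene matched a RefSeq gene. No gene was named from a probe set with several genes. No coordinates are given, since the values carry none. With several probe sets for a gene, the one with the highest mean over the 8 arrays stood for it, which gave 13356 genes.

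The main test was limma 3.58.1 in R 4.3.3 (lmFit with a mean per group over all 8 arrays, contrasts, eBayes with default settings, two-sided, Benjamini-Hochberg adjustment over 22746 probe sets); a probe set was called at an adjusted p under 0.05. The 6 contrasts were cold in wild type, cold in L20, L20 minus wild type before cold, the same after cold, the difference of the cold responses, and the mean of both genotype differences. Standard errors are those of limma's moderated test. Adjusted p-values in the text are limma's with that adjustment, unless camera is named.

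Before the data were examined, 21 gene lists with 342 loci were fixed, together with the tests, the alternatives and the rule for naming genes; additions made later are named as such. Only 46 of these loci had a named probe set, so the 7 lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a contrast, and again with an estimated correlation, with fry and with the replicate block. Members were also adjusted over the list alone, which corrects nothing where a list had 1 measured gene. The rule for naming took, per comparison, the 8 largest increases and 8 largest decreases among called probe sets with 1 gene whose replicates did not overlap between the groups, all of them if there were fewer, and the 5 smallest p-values in each direction if none was called. It added the 4 members with the smallest p of each list described, some left out for space, and always CBF1, CBF2, CBF3, COR15A, COR15B, COR47, RD29A and KIN1, of which 3 of 8 could be measured. TabZIP6, a wheat gene, had no probe set, so its own level was not analysed here. Applying this rule to the fit with the replicate block, and testing gene families by the shared start of their symbols, the block together with trend and robust settings, and leaving out arrays from the blocked fit, were chosen after seeing the data.

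All groups share replicate numbers 1 and 2, and whether these pair the arrays was checked before the calls of both fits were compared. The difference of replicate 1 minus replicate 2 correlated between every 2 of the 4 groups, at 0.341 to 0.837 over the tested probe sets and at 0.488 to 0.894 over 45 control probe sets for RNA added during processing. The numbers were therefore treated as a shared batch, a pairing taken from the data and not stated in the labels. A fit with the replicate number as a block is given beside the main one where it changed a call over all probe sets or of a list by camera, or moved a count by over 1.5 times, and changes within each replicate number are given for selected genes.

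Both fits were tested on simulated arrays with the real means, residual spread and replicate effect of the 22746 probe sets, in which 200 were changed between wild type before and after cold. The replicate effect was made the same in all 4 groups, and the spread was that of the blocked fit. This favours the blocked fit in advance, so its rates may be better here than in the real data. Of those changed 4-fold, the main fit recovered 62.0% with 0 false calls and the blocked fit 98.0% with 21 false among 217 calls. Of those changed 2-fold, the main fit recovered 0 and the blocked fit 55.5% with 16 false among 127 calls. The main counts therefore cover large changes only. In a simulation of camera on cold in wild type, a list of 6 probe sets shifted 2-fold was found, and 9 of 100 unshifted lists had p under 0.05. These lists were random probe sets with independent noise, so it does not cover lists of genes that vary together.

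The alternatives were eBayes with trend and robust settings, only the arrays of the groups compared, the replicate block, leaving out the dimmest 40% of probe sets, equal array medians, quantile normalization, a 2-fold minimum, an adjusted p under 0.01, 1 probe set per gene, and leaving out each array in turn. When an array is left out, the lone array of its group is taken to vary like the other groups.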

Results

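Gene expression was measured on Affymetrix arrays of the Arabidopsis genome, on which a gene is read by a group of short probes called a probe set. The samples were whole seedlings aged 10 days. Wild-type seedlings of ecotype Col-1 were set against L20, a line that overexpresses TabZIP6, a wheat transcription factor of the basic leucine zipper (bZIP) family. Both were sampled at 22 °C before cold and again after 6 h at 4 °C. Each of the 4 groups had 2 biological replicates, which gave 8 arrays. The labels do not say how the replicates were grown apart, so the p-values measure the spread between these samples. The tests covered 22746 probe sets, of which 13513 carried the name of 1 gene, and the array medians ran from 4.95 to 5.06 on the log2 scale.

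Replicate number and cold both separated the arrays. Across probe sets, which are not independent replicates, wild type and L20 after cold correlated at 0.993 in replicate 1 and at 0.992 in replicate 2. The replicates within a group correlated less, at 0.959 for wild type and 0.955 for L20 after cold, and at 0.968 and 0.959 before cold. The number of arrays limits the precision: an exact two-sided permutation test of 2 against 2 arrays cannot go below p = 0.333, so the tests below come from limma models fitted over all probe sets.

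**Figure D1:**
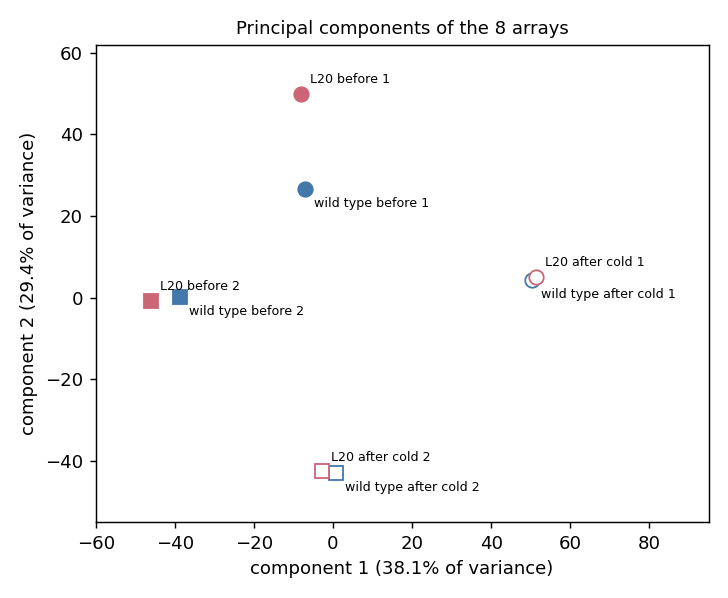
Principal components of the 8 arrays over 22746 probe sets, with the share of variance of each component on its axis (38.1% and 29.4%). Circles are replicate 1 and squares replicate 2, filled symbols are before and open symbols after cold, blue is wild type and red is L20; the L20 and wild-type arrays after cold lie almost on top of each other within each replicate number.

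The first comparison asked which genes responded to 6 h of cold in wild-type seedlings. The cold-regulated (COR) genes rose together: LTI30, which encodes a dehydrin, went from 5.71 ± 0.83 to 11.87 ± 0.31 (log2 signal, SD, n = 2), a 71.7-fold increase. COR15A and COR15B, whose products protect chloroplast membranes during freezing, rose 4.91-fold and 5.72-fold, and the dehydrin gene COR47 rose 4.77-fold. All 6 measured members of the list of CBF-regulon and COR genes were higher after cold. The transcription factor gene ORA47, part of the jasmonate response, fell by 4.32 on the log2 scale, from 8.60 ± 0.44 to 4.27 ± 0.52, and AT4G27280 fell from 10.58 ± 0.31 to 6.46 ± 0.09.

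In numbers, 121 probe sets changed in wild type, 92 upwards and 29 downwards, and all of them by at least 2-fold. Of the 121, only 53 carried the name of 1 gene. The increases and decreases below are ranked among those 53, by the rule for naming, and not among all calls. Besides LTI30, the strongest increases were those of AT1G16850 (log2 change 4.75 ± 0.35, SE), AT1G48100 (4.35), AT1G51090 (4.34), AT3G55580 (3.77), AT4G12000 (3.70), AT1G73480 (3.40) and AT1G10410 (3.23). Their limma adjusted p-values lay between 0.00615 for AT3G55580 and 0.0289 for AT1G73480. After ORA47 (-4.32 ± 0.63, limma adjusted p = 0.0490) and AT4G27280 (-4.12 ± 0.35), the strongest decreases were those of AT1G72920 (-2.91), AT3G26510 (-2.75), AT2G25200 (-2.44), AT1G47400 (-2.08), AT5G56100 (-2.04) and AT3G10120 (-1.87). Each of these genes moved in its direction in both replicates, which the rule for naming required, so it is not separate evidence. In replicates 1 and 2, LTI30 changed by 6.53 and 5.80 and ORA47 by -4.26 and -4.38.

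Of the 6 measured CBF-regulon and COR genes, 4 rose in wild type by the adjustment over all probe sets and 6 when adjusted over the list alone. COR27 (1.70 ± 0.33) and COR28 (1.47 ± 0.35), cold-induced regulators of the circadian clock, were the members that missed the adjustment over all probe sets. The list shifted upwards by a median of 2.28 (camera, Benjamini-Hochberg adjusted p = 1.89e-18), and the call held with an adjusted p = 0.0382 with an estimated correlation. Over 11 single alternatives the adjusted p ran from 1.79e-17 to 0.0382, while the estimate and the replicate block together gave an adjusted p = 0.202 with an estimated correlation. CBF1, CBF2, CBF3 and RD29A were on no named probe set and KIN1 was on a probe set of several genes, so they were not analysed here.

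Of the starch, sucrose and raffinose genes, 3 of 23 were measured. DPE1, the plastid disproportionating enzyme of starch breakdown, differed by -1.47 ± 0.23 and PWD, an enzyme that phosphorylates starch, by -0.65 ± 0.25. Both fell when adjusted over the list alone (limma adjusted p = 0.00106 and 0.0496), and 0 of 3 members passed over all probe sets, with 2 of 3 at an unadjusted p under 0.05. With the replicate block 1 member, DPE1, passed over all probe sets. SBE2.2, a starch branching enzyme, stood at 0.24 ± 0.34. The list of starch, sucrose and raffinose genes, with 3 measured members, shifted downwards (camera adjusted p = 0.00770), which was lost at an adjusted p = 0.128 with an estimated correlation. Over 11 alternatives its adjusted p ran from 0.00145 to that value, and the list missed without replicate 2 of wild type before or after cold (camera adjusted p = 0.0537 and 0.0921). The iron-deficiency transcription factor gene bHLH101 differed by -1.54 ± 0.31 and PYE, a regulator of the same response, by -0.86 ± 0.27. Both fell when adjusted over the list alone (limma adjusted p = 0.00354 and 0.0145), and with the replicate block bHLH101 also passed over all probe sets. GI, a clock gene and the 1 measured member of its list, stood 1.12 ± 0.30 higher after cold and missed the test over all probe sets (limma adjusted p = 0.287).

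The test was limma with a mean per group and Benjamini-Hochberg adjustment over 22746 probe sets. With the replicate number as a block the count was 357 probe sets, 230 up and 127 down, and the 121 were among them. The rule for naming genes, applied to that fit after the data were seen, added AT4G36010 (4.37) and AT5G47060 (3.86) as increases and AT1G23390 (-3.77), AT5G03230 (-3.42), AT2G20670 (-3.35) and AT1G32920 (-2.75) as decreases. With 1 array left out the count ran from 0 without replicate 2 of wild type after cold to 91; it was 6 without replicate 1 of that group and 15 without either wild-type array before cold.

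The second comparison put the same question to L20. AT3G44450 rose 14.7-fold, from 3.72 to 7.60 in log2 signal, and AT3G17130 rose 12.1-fold. Of the 8 strongest increases named for wild type, 4 also passed in L20: AT1G48100 rose 10.4-fold, AT3G55580 10.3-fold, AT1G73480 10.1-fold and AT1G10410 7.48-fold. The other 4 did not pass there, LTI30 (limma adjusted p = 0.275), AT1G16850 at 0.30 ± 0.35 (0.994), AT4G12000 at 1.76 ± 0.34 (0.109) and AT1G51090 at 1.90 ± 0.42 (0.155), of which AT1G51090 passed with the replicate block. The cold responses of the COR genes in L20 did not pass the test over all probe sets: LTI30 stood at 1.64 ± 0.47, COR15A at 0.52 ± 0.26, COR15B at 0.50 ± 0.28 and COR47 at -0.23 ± 0.26 (log2 difference, SE). AT4G30470 fell 9.20-fold in L20.

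In L20, 86 probe sets changed, 63 upwards and 23 downwards, all by at least 2-fold. Of the 86, only 32 carried the name of 1 gene, and genes were named among these. AT1G65490 (2.99 ± 0.32) and AT4G32190 (2.81 ± 0.27) completed the strongest named increases. The decreases named by the rule were those of AT4G30470 (-3.20 ± 0.26, limma adjusted p = 0.0122), AT4G33490 (-2.10), AT3G19850 (-1.85), AT2G46490 (-1.76), AT5G07580 (-1.58) and AT4G21620 (-1.34). The replicate block added 11 named genes, 4 upwards and 7 downwards, chosen by the same rule after the data were seen. They included BETA-VPE, a vacuolar processing enzyme (3.84), AT3G44970 (3.37), IAA29 (-3.17), EXO (-2.69) and GH3.5 (-2.36). Their limma adjusted p-values with the block lay between 0.00280 and 0.0488, and over 11 alternatives per gene between 0.00280 and 0.965.

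As a list, the auxin and gibberellin growth genes had a median difference of -1.98 with cold in L20 (camera adjusted p = 0.000972), lost at an adjusted p = 0.131 with an estimated correlation. Over 11 alternatives the adjusted p ran from 0.000229 to that value. IAA29, an Aux/IAA repressor of auxin signalling, went from 9.10 ± 0.49 to 5.93 ± 0.94 (log2 signal, SD, n = 2). GH3.3 stood at -1.98 ± 0.67 and GH3.5 at -2.36 ± 0.81 (log2 difference, SE), and both encode enzymes that join auxin to amino acids. Of the 5 measured members, limma called 0 over all probe sets, with 3 at an unadjusted p under 0.05, and 2 with the replicate block. These 3 passed downwards when adjusted over the list alone. In wild type the same list had a median of -0.38 and camera gave an adjusted p = 0.126, or 0.0351 with the replicate block, which was lost at an adjusted p = 0.208 with an estimated correlation in the fit with the block.

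Of the 6 CBF-regulon and COR genes, limma called 0 in L20 over all probe sets, with and without the replicate block, and 2 had an unadjusted p under 0.05. These 2, LTI30 and COR28, passed when adjusted over the list alone. The list shifted upwards by a median of 0.54 (camera adjusted p = 0.000972), lost at an adjusted p = 0.20 with an estimated correlation. The starch enzyme genes DPE1 (-1.36 ± 0.23) and PWD (-0.66 ± 0.25) both fell when adjusted over the list alone, and DPE1 also over all probe sets with the replicate block. For the list camera gave an adjusted p = 0.0807, with 0.0231 to 0.335 over 11 alternatives, of which only fry passed. The 3 measured flavonoid genes, DFR, UF3GT and UGT75C1, shifted upwards as a list by a median of 0.43 (camera adjusted p = 0.0235, and an adjusted p = 0.20 with an estimated correlation), and limma called 0 of them with and without the replicate block, with 0 and 1 at an unadjusted p under 0.05. This list missed without replicate 1 of L20 before or after cold (camera adjusted p = 0.241 and 0.325). GI stood 1.45 ± 0.30 higher after cold in L20 and missed the test over all probe sets (limma adjusted p = 0.122, and 0.0221 to 0.5003 over 11 alternatives).

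With the replicate block the count for L20 was 580 probe sets, 290 up and 290 down. With 1 array left out it ran from 0 without replicate 1 of L20 before cold to 34 without either wild-type array before cold; it was 1 without either L20 array after cold, 11 without replicate 2 of L20 before cold and 28 without either wild-type array after cold.

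The cold responses of wild type and L20 were then set against each other. The calls that both had in common included AT1G48100, AT3G55580, AT1G73480 and AT1G10410. Of the calls, 40 increases and 6 decreases were shared. With the replicate block 140 increases and 59 decreases were shared, and 2 increases in wild type were decreases in L20. After cold the arrays of both lines correlated at 0.993 and 0.992 within a replicate number, so the calls were not independent and no chance overlap is given. Across the 22746 probe sets, which are not independent replicates, the responses correlated at 0.646, and at 0.453 and 0.476 when the response of wild type in 1 replicate number was set against that of L20 in the other. Leaving out 1 array gave 0.507 to 0.627. Within a line, the responses of replicate 1 and replicate 2 correlated at 0.526 in wild type and 0.600 in L20. The values of 0.453 and 0.476 between the lines are to be read against these.

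**Figure D2:**
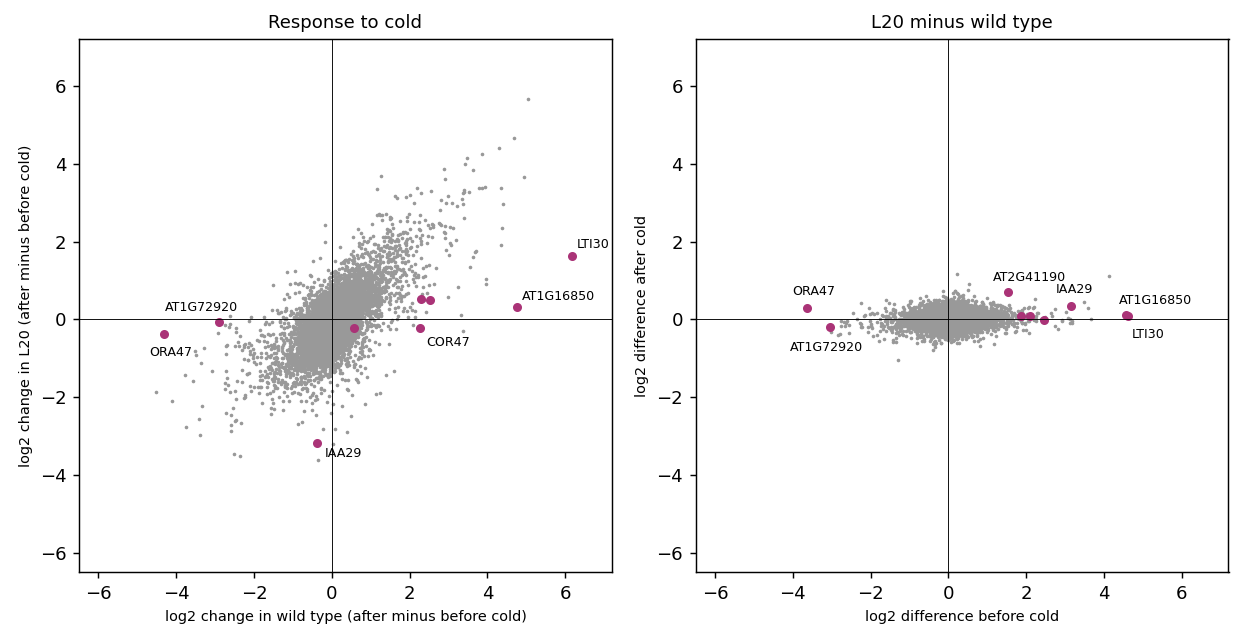
Each grey point is 1 of 22746 probe sets and the purple points are named genes. Left: log2 change after cold in wild type (horizontal) and in L20 (vertical), where LTI30 lies at 6.16 and 1.64. Right: log2 difference of L20 minus wild type before cold (horizontal) and after cold (vertical), where LTI30 lies at 4.61 and 0.08; the differences spread widely before cold and little after it.

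The third comparison asked what distinguished L20 from wild type before any cold. AT1G16850 was 23.7-fold higher in L20, at 9.32 ± 0.17 against 4.76 ± 0.11 (log2 signal, SD, n = 2), close to its level in chilled wild type (9.50 ± 0.53). AT4G30470 was 9.12-fold higher in L20, and AT1G72920 was 8.25-fold lower. Of the COR genes, LTI30, COR47 and COR15B missed before cold over all probe sets in the main fit and passed with the replicate block. COR15A missed with and without it. Of 11 alternatives, LTI30 passed in 3, COR47 in 2 and COR15B in 1. LTI30 was at 10.31 ± 0.75 against 5.71 ± 0.83, COR47 at 12.57 ± 0.08 against 10.11 ± 0.52, COR15B at 10.62 ± 0.28 against 8.53 ± 0.19 and COR15A at 9.92 ± 0.32 against 8.07 ± 0.34. The auxin gene IAA29 was at 9.10 ± 0.49 in L20 against 5.96 ± 0.20 in wild type.

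By limma over all probe sets, 4 passed before cold, 3 higher and 1 lower in L20. The 3 with a gene name were AT1G16850 (4.56 ± 0.35, adjusted p = 0.0303), AT4G30470 (3.19 ± 0.26, 0.0333) and AT1G72920 (-3.04 ± 0.22, 0.0303). The fourth, higher in L20, had no gene name here. With the replicate block the count was 38, with 22 higher and 16 lower. That fit takes 1 spread for all 4 groups, although the lines differed unequally. The standard deviation of L20 minus wild type over probe sets was 0.515 and 0.411 before cold and 0.204 and 0.209 after cold. The p-values with the block may therefore be too low before cold. The block added 13 named genes. The 6 that were higher in L20 were LTI30 (4.61 ± 0.47), COR47 (2.45), COR15B (2.09), GH3.5 (1.88), the expansin gene EXPA16 (1.81) and AT2G41190 (1.52). The 7 that were lower were ORA47 (-3.65 ± 0.63), ARL, a gene of cell expansion (-2.78), AT1G47400 (-1.97), AT3G15760 (-1.83), AT2G30600 (-1.76), AT5G24210 (-1.61) and AT5G59080 (-1.35). Their limma adjusted p-values with the block lay between 0.0164 and 0.0494, and over 11 alternatives per gene between 0.0164 and 1.00. For the COR genes among them that range was narrower: the limma adjusted p ran from 0.0313 to 0.360 for LTI30, from 0.0190 to 0.442 for COR47 and from 0.0164 to 0.496 for COR15B.

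**Figure D3:**
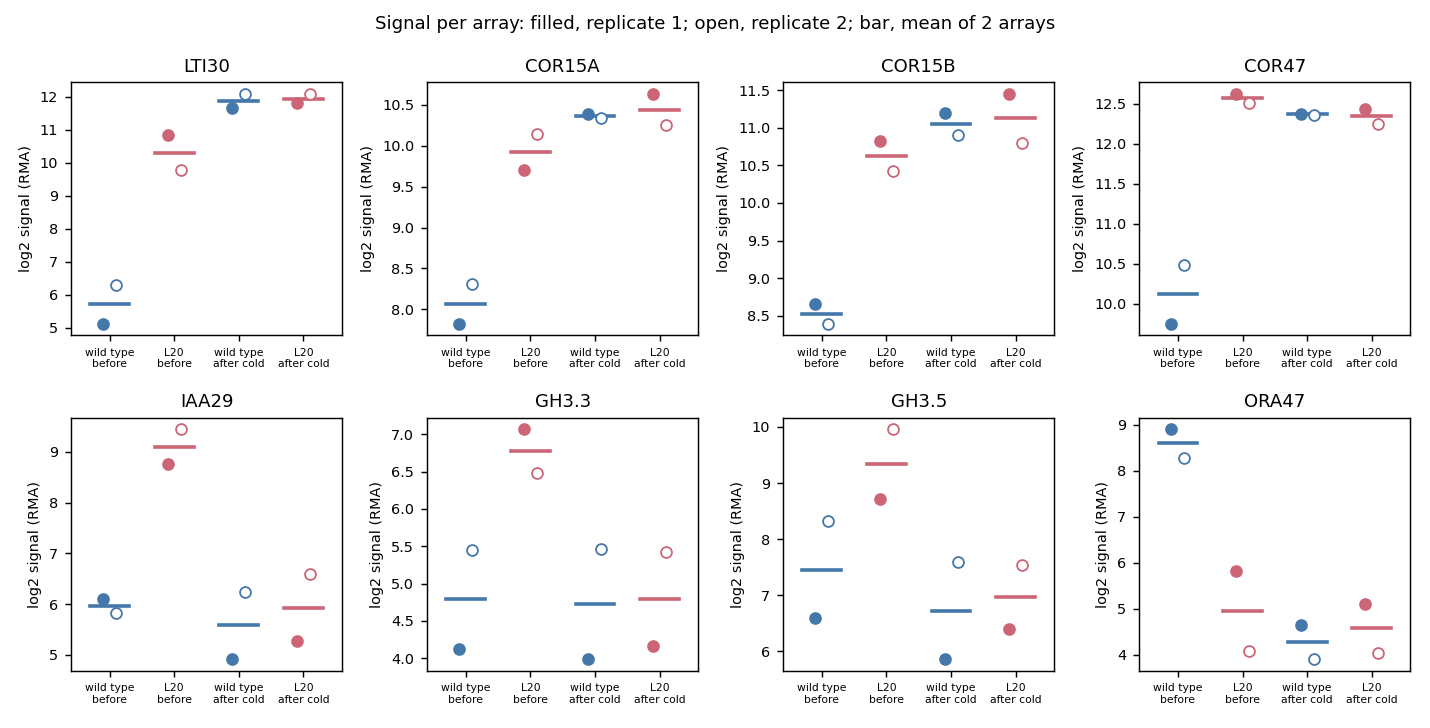
Log2 signal of 8 genes on each of the 8 arrays; filled circles are replicate 1, open circles replicate 2, bars the mean of the 2 arrays, blue is wild type and red is L20, and the vertical axes differ between genes and do not start at 0. LTI30, COR15A, COR15B and COR47 averaged between 9.92 and 12.57 in L20 before cold and between 5.71 and 10.11 in wild type before cold, while IAA29 averaged 9.10 in L20 before cold and between 5.58 and 5.96 in the other groups.

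Taken as a list, the CBF-regulon and COR genes were higher in L20 before cold, by a median of 1.97 (camera adjusted p = 5.32e-11), lost at an adjusted p = 0.0988 with an estimated correlation. Over 11 alternatives the adjusted p ran from 1.19e-10 to that value. Of its 6 measured members, 5 were higher when adjusted over the list alone. Over all probe sets limma called 3 with the replicate block and 0 without it, with 5 at an unadjusted p under 0.05. COR28 was the exception, at -0.45 ± 0.35. The auxin and gibberellin growth genes were higher too, by a median of 1.88 (camera adjusted p = 0.0214), lost at an adjusted p = 0.171 with an estimated correlation. The auxin list also missed without either wild-type array before cold or replicate 2 of L20 before cold (camera adjusted p = 0.0559 to 0.163). IAA29 (3.14 ± 0.57) passed when adjusted over the list alone (limma adjusted p = 0.00453). GH3.3 (1.98 ± 0.67) and GH3.5 (1.88 ± 0.81) did so with the replicate block, while EXPA8 stood at -0.55 ± 0.46. The late-embryogenesis protein gene LEA4-5, of the abscisic acid response, and the stress zinc-finger gene ZAT10 were each the 1 measured member of a list, and both missed the test over all probe sets (limma adjusted p = 0.861 and 0.531). LEA4-5 stood 2.73 and 1.66 higher in L20 in the replicates, and ZAT10 stood at -2.29 ± 0.62. The iron gene bHLH101 (-1.16 ± 0.31) was lower when adjusted over the list alone (limma adjusted p = 0.0156) and missed over all probe sets (0.522). For the flavonoid genes camera pointed downwards (adjusted p = 0.551), while their median, which was UGT75C1, stood at 0.01.

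Leaving out any 1 of the 8 arrays, of either line before or after cold, turned the count of 4 into 0 by limma, where 1259 probe sets had an unadjusted p under 0.05 with all arrays and the replicate block called 38. Quantile normalization gave 17 probe sets, 10 higher and 7 lower. If no probe set differed, 1137.3 would be expected at an unadjusted p under 0.05. The 1259 of the main fit lay near that number, and the replicate block gave 2535. After cold the main fit gave only 19, so its count can lie well below 1137.3. Nearness to that number is therefore weak evidence of no difference, while the p-values with the block may be too low before cold.

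The fourth comparison set L20 against wild type after 6 h at 4 °C. LTI30 stood at 11.95 ± 0.21 in L20 and 11.87 ± 0.31 in wild type, COR15A at 10.44 ± 0.27 and 10.36 ± 0.03, COR15B at 11.12 ± 0.46 and 11.05 ± 0.21, and COR47 at 12.34 ± 0.14 and 12.37 ± 0.01 (log2 signal, SD, n = 2). IAA29 was at 5.93 ± 0.94 and 5.58 ± 0.94. The 5 named genes with the smallest p on the higher side of L20 were AT2G41190 (0.71 ± 0.19), AT1G70280 (0.73), AT3G20280 (0.61), AT3G51000 (0.49) and AT1G03180 (0.49). On the lower side they were AT3G01820 (-0.68 ± 0.17), AT1G74780 (-0.61), AT4G20000 (-0.52), AT5G24240 (-1.06) and AT5G52710 (-0.41).

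These did not pass: limma called 0 probe sets after cold, with and without the replicate block, and 19 and 129 had an unadjusted p under 0.05, in order without and with the block. Both counts lay far below the 1137.3 expected if no probe set differed. The spread pooled over all groups was therefore too wide for these arrays, and the 0 calls are weak evidence of no difference. The difference after cold had a standard deviation of 0.204 over probe sets in replicate 1 and 0.209 in replicate 2, against 0.515 and 0.411 before cold. The list of CBF-regulon and COR genes had a median difference of 0.02 after cold and its camera test pointed downwards (adjusted p = 0.951). The other 6 tested lists did not pass after cold by camera either, at adjusted p-values from 0.220 for the flavonoid genes to 0.951. The flavonoid list passed without replicate 2 of L20 after cold (camera adjusted p = 0.0207, and 0.0207 to 0.992 over 11 alternatives).

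The design also asks whether cold acted differently in L20 and wild type. As a list, the CBF-regulon and COR genes had a median difference of -1.90 between the cold responses, L20 minus wild type (camera adjusted p = 2.03e-12), lost at an adjusted p = 0.0794 with an estimated correlation. Over 11 alternatives the adjusted p ran from 7.32e-11 to that value, and 5 of 6 members lay below 0, with COR28 at 0.36. Taken the same way, the response of LTI30 differed by -4.53 ± 0.67 (log2, SE), and those of COR47, COR15B and COR15A by -2.48 ± 0.36, -2.02 ± 0.39 and -1.78 ± 0.36. As the lines hardly differed in these genes after cold, these values largely repeat the difference before cold with its sign turned. They are not separate evidence. The auxin and gibberellin growth genes differed by a median of -1.63 (camera adjusted p = 0.0410), lost at an adjusted p = 0.217 with an estimated correlation. IAA29 stood at -2.79 ± 0.80 and GH3.3 at -1.92 ± 0.94, and over 11 alternatives the list's adjusted p ran from 0.00418 to 0.232. This list missed without either wild-type array before cold, replicate 2 of L20 before cold, replicate 2 of wild type after cold or replicate 1 of L20 after cold (camera adjusted p = 0.0579 to 0.199). The flavonoid genes, at an adjusted p = 0.239, passed only without replicate 2 of L20 after cold (0.0222, and 0.0222 to 0.870 over 11 alternatives).

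Gene by gene, limma called 0 probe sets for this difference, with and without the replicate block. At an unadjusted p under 0.05 there were 497 and 1215, against 1137.3 expected if no probe set differed. When adjusted over the list alone, 4 of the COR genes passed, LTI30, COR47, COR15A and COR15B. Of the auxin and gibberellin growth genes, 0 did so without and 3 with the replicate block, with 1 and 3 at an unadjusted p under 0.05. bHLH101 (1.47 ± 0.44) also passed when adjusted over the list alone, while ZAT10, alone on its list, stood at 2.19 ± 0.88 (limma adjusted p = 1.00). The named genes with the smallest p were AT1G16850 (-4.44 ± 0.49, limma adjusted p = 0.297), AT4G30470 (-3.23) and AT3G01820 (-1.49) besides LTI30 and COR47 among those with the lower response in L20. On the other side they were AT1G72920 (2.84 ± 0.31, 0.297), AT1G47400 (2.13), AT3G15760 (1.77), AT2G30600 (1.46) and AT3G10120 (1.33).

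Averaged over both temperatures, AT1G16850 (2.34 ± 0.25), LTI30 (2.34), AT4G30470 (1.58), COR47 (1.21) and AT2G41190 (1.12) stood higher in L20, and AT1G72920 (-1.62 ± 0.15), ARL (-1.58), AT2G30600 (-1.03), AT1G47400 (-0.91) and AT2G29320 (-0.70) lower. An average does not mean a difference at both temperatures. After cold alone the difference was 0.12 for AT1G16850, 0.08 for LTI30, -0.03 for COR47, -0.20 for AT1G72920 and 0.71 for AT2G41190. COR15A and COR15B stood at 0.97 ± 0.18 and 1.09 ± 0.20. None of these genes passed: limma called 0 probe sets, with and without the replicate block. At an unadjusted p under 0.05 there were 636 and 1435, against 1137.3 expected if no probe set differed. The CBF-regulon and COR genes were higher by a median of 1.03 (camera adjusted p = 6.24e-11, and an adjusted p = 0.0999 with an estimated correlation), and the auxin and gibberellin growth genes by 1.02 (camera adjusted p = 0.0217, and an adjusted p = 0.172 with an estimated correlation). After cold alone the medians of both lists were 0.02 and 0.11, so these averages largely repeat the difference before cold. The auxin list missed without replicate 1 of wild type before cold, replicate 2 of L20 before cold or replicate 2 of L20 after cold (camera adjusted p = 0.0728 to 0.207).

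Genes of endoplasmic reticulum folding (4 measured), heat shock genes (3) and root markers (3) passed camera in none of the 6 comparisons with all arrays. Without replicate 2 of wild type before cold, the endoplasmic reticulum list passed for L20 against wild type before cold (camera adjusted p = 0.0252), for the difference of the cold responses (0.0244) and for the average over temperatures (0.0491). Over 11 alternatives its adjusted p ran up to 0.895, 0.993 and 0.780 there. Medians of these lists for cold in wild type were 0.11, 0.10 and 0.20, and for L20 minus wild type before cold 0.35, 0.23 and 0.26. For cold in L20 the heat shock genes had a median of -0.02 while camera pointed upwards (adjusted p = 0.734). The other 12 lists had 1 or 2 named members, 19 genes in all, and were not tested as lists. They covered regulators of the CBF genes, other early cold transcription factors, the abscisic acid response, the clock, photosynthesis, sugar starvation, Arabidopsis bZIP genes of groups C and S1, proline, salicylic acid, jasmonate, iron and seed markers. Over all probe sets limma called 0 of these 19 genes in any comparison, and with the replicate block 1, bHLH101 for cold in wild type. At an unadjusted p under 0.05 there were 4 for cold in wild type, 4 for cold in L20 and 3 for L20 against wild type before cold. In the 8 lists with 2 members, 3, 2 and 1 genes passed in these comparisons when adjusted over the list alone, and 3, 5 and 2 with the replicate block. The other 4 lists had 1 member, where that adjustment corrects nothing. MCCA, a carboxylase subunit of leucine breakdown on the sugar starvation list, fell when adjusted over the list alone with cold in wild type (-1.18 ± 0.38) and in L20 (-1.33 ± 0.38). The lists of CBF genes and flower markers had 0 named members.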

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

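The tests of a constant effect of the line, of shared material, of noise, of a cold-like state limited to the strongest differences, of array processing, of RNA integrity, of time of day and of other splits of the arrays were chosen only after the result was seen.

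The cold responses of wild type and L20 differed for 2 gene lists by camera with the preset correlation, in the test of the difference itself. The CBF-regulon and COR genes had a median difference of -1.90 log2 units, L20 minus wild type (camera adjusted p = 2.03e-12), and 5 of 6 members lay on that side. This was lost with an estimated correlation (camera adjusted p = 0.0794) and by fry (adjusted p = 0.0731). The call therefore rests on the preset correlation. For the auxin and gibberellin growth genes the median was -1.63 (camera adjusted p = 0.0410, and an adjusted p = 0.217 with an estimated correlation, passing in 4 of 11 alternatives), with 3 of 5 members on that side. Before cold both lists were higher in L20 by camera (adjusted p = 5.32e-11 and 0.0214), which was lost at an adjusted p = 0.0988 and 0.171 with an estimated correlation, and after cold their medians were 0.02 and 0.11.

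This pattern, a larger difference between the lines before cold than after it, was weighed first. The 38 probe sets called before cold with the replicate block had a median difference of 1.93 before cold. After cold it was 0.0784 in the same direction. This would argue against a constant effect of the line only if the cold arrays of both lines hold different material. That is not known, so a constant effect stays open. The differences before cold of both replicates correlated at 0.276, short of the 0.3 first set to exclude noise that is independent between the replicates. Such noise is argued against by a bound added after that was seen. By it, 214 probe sets differed 2-fold in both replicates in 1 direction, against 31 in opposite directions. A general cold-like state of unchilled L20 is argued against. The difference before cold correlated with the wild-type cold response of the other replicate number at 0.0174 and 0.0530. Noise limits how high these values could go. Between the replicates, the difference before cold correlated at only 0.276 and the wild-type cold response at 0.526. A weak general cold-like state is therefore not excluded. Before cold, 173 and 113 probe sets differed at least 4-fold in replicate 1 and in replicate 2. Their median wild-type cold response in the other replicate number, signed by that difference, was 0.493 and 1.09. A cold-like state of L20 limited to these probe sets is therefore a candidate explanation. The group of wild type before cold entered both differences, so an unusual level in that group would give the same sign. These values cannot separate the 2 explanations. Whether the arrays of both lines after cold hold the same material cannot be told apart from a true lack of difference. The differences of both replicates correlated at -0.0125. Yet the 38 probe sets lay further in their direction after cold than all but a share of 0.0024 of 10000 random sets. Random sets do not cover genes that vary together, so this share may be too low. Of the 38, 16 kept their direction after cold in both replicates. An effect of TabZIP6 that shows before cold stays open as well, and a swap or shared source before deposit was not tested by any other value.

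The second pattern is that arrays of the same replicate number deviated together. Over 45 control probe sets for RNA added during processing, the replicate differences of the groups correlated at 0.488 to 0.894, which is consistent with processing of the arrays in batches by number. RNA integrity stays open: the signal at the 3 prime end minus that at the 5 prime end of actin, GAPDH and ubiquitin moved in 1 direction between the replicate numbers in 8 of 12 combinations of gene and group, and for GAPDH it was higher in replicate 2 in all 4 groups, by 0.0488 to 0.784. A biological difference between the plantings of both replicates stays open, untested.

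The third pattern is the cold response itself, which time of day may share, because no array was taken 6 h later without cold. GI, the 1 clock gene with a name here, stood higher after cold by 1.12 in wild type and 1.45 in L20, neither past limma over all probe sets (adjusted p = 0.287 and 0.122), and with no unchilled array at that hour cold and hour cannot be told apart for it.

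For L20 against wild type averaged over both temperatures, limma called 0 probe sets, with 636 at an unadjusted p under 0.05 and 0 with the replicate block. Since the real split called 0, each of the 18 splits of the arrays within each temperature gave at least as many by construction, so the comparison says nothing about chance, and 18 splits are too few for a share under 0.05. The highest of the other splits gave 4773, and it was the split by replicate number, which points to a structure of the samples.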

How the results depend on the processing

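The replicate block together with trend and robust settings, and leaving out arrays from the blocked fit, were chosen only after the result was seen.

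For cold in wild type, where 121 probe sets were called, the replicate block gave 357, quantile normalization 183, 1 probe set per gene 41, only the arrays compared 65, an adjusted p under 0.01 gave 10, the block with trend and robust settings 574, and leaving out 1 array 0 to 91. For cold in L20, with 86, these were 580, 204, 6, 0, 7 and 784, and 0 to 34. For L20 against wild type before cold, with 4, the block gave 38, quantile normalization 17, only the arrays compared 1, an adjusted p under 0.01 gave 0, the block with trend and robust settings 139, and leaving out any 1 array gave 0. The block with trend and robust settings also called 9 for the difference of the cold responses and 20 for the average over temperatures, where limma without the block called 0, with 497 and 636 at an unadjusted p under 0.05. With the replicate block, leaving out 1 array gave 0 to 850 for cold in wild type, 0 to 1721 for cold in L20, 0 to 615 before cold, 0 to 5 for the difference of the cold responses and 0 to 28 for the average over temperatures. A stricter threshold lowers the count by construction; for the other changes the cause was not tested. Trend and robust settings (111, 81 and 6), leaving out the dimmest 40% (163, 126 and 5) and equal medians (132, 104 and 4) kept these counts within 1.5 times. After cold, each setting run called 0 by limma, with 19 at an unadjusted p under 0.05. The correlation of the cold responses, 0.646, was 0.675 without the dimmest 40% of probe sets and 0.507 to 0.627 with 1 array left out.

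With 1 array left out, values near 0 changed sign. After cold, L20 minus wild type ranged from -0.11 to 0.27 for COR15A, from -0.25 to 0.40 for COR15B and from -0.12 to 0.0675 for COR47. Cold in wild type ranged from -0.0291 to 0.51 for SBE2.2, from -1.05 to 0.29 for IAA29, from -0.80 to 0.67 for GH3.3 and from -1.60 to 0.14 for GH3.5. Cold in L20 ranged from -1.07 to 1.197 for LEA4-5 and from -0.21 to 0.0755 for bHLH101. Before cold, L20 minus wild type ranged from -0.97 to 0.0719 for COR28, from -0.33 to 0.84 for MCCA, from -0.22 to 0.0613 for DPE1 and from -0.82 to 0.0106 for SBE2.2. The difference of the cold responses ranged from -0.16 to 0.88 for COR28. PWD before cold was -0.0162 with quantile normalization, and the cause was not tested.

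Of the named genes called, 0 of 16 for cold in wild type, 0 of 14 in L20 and 0 of 3 before cold passed limma with each array left out in turn. Beyond the calls given beside the results, the replicate block changed no other call of a fixed list by camera. Over all probe sets, of 104 genes named by the rule or measured on a list, it added calls for 17 with cold in wild type, 23 in L20 and 15 before cold, and ended 0. Among members of lists with at least 2 measured genes, adjusted over the list alone, it added 15 calls to 37 and ended 0. Fry tests whether the genes of a list changed, while camera tests whether they changed more than the other genes, so their calls answer different questions. Fry lost 6 list calls. They were the COR and flavonoid lists for cold in L20 (fry adjusted p = 0.129 and 0.135). The others were the COR and auxin lists for the difference of the cold responses (0.0731 and 0.232) and the average (0.0624 and 0.0995). Fry added the starch list for cold in L20 (0.0231). With 1 array left out, camera lost 15 list calls and gained 5, given beside the results. Signal over background was not analysed, so a limit for dim probe sets is not known.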

Other observations

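The tests of gene families and of the genes of the plastid genome were chosen only after the result was seen.

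Aldehyde dehydrogenase genes, whose enzymes oxidise reactive aldehydes, had values below 0 for cold in L20 in 7 of 8 measured members, with a median of -0.70 (camera adjusted p = 0.00542 over 46 families, and an adjusted p = 0.683 with an estimated correlation). Limma called 0 of the 8 over all probe sets, with and without the replicate block, where 4 and 5 had an unadjusted p under 0.05, and 2 and 4 passed when adjusted over the family alone. ALDH2C4 stood at -1.18, ALDH7B4 at -1.17 and ALDH6B2 at -0.85. In wild type the median was -0.20 (camera adjusted p = 0.286), and the difference between the lines had an adjusted p = 0.256. It was the only family of the 46 past camera without the replicate block in the 6 comparisons.

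Genes of the plastid genome, which encode parts of the photosynthetic and gene expression machinery of the chloroplast, had values above 0 for L20 minus wild type before cold in 60 of 69 members, with a median of 0.26. Over all tested probe sets the median of this difference was 0.037, and 0.102 without the dimmest 40%. With quantile normalization it was 0.0034. Bright probe sets thus leaned towards L20 before cold, and the plastid genes were not tested after quantile normalization. Limma called 0 of the plastid genes over all probe sets or over this group alone, with and without the replicate block, where 1 and 3 had an unadjusted p under 0.05. Camera gave an adjusted p = 0.136, and 0.00262 with the replicate block, which was lost at an adjusted p = 0.829 with an estimated correlation in the fit with the block. For the difference of the cold responses, L20 minus wild type, their median was -0.21 with 10 of 69 above 0 (camera adjusted p = 0.169, and 0.0451 with the replicate block), lost at an adjusted p = 0.971 with an estimated correlation in that fit. Averaged over both temperatures the median was 0.12 with 59 of 69 above 0 (camera adjusted p = 0.148, and 0.0236 with the replicate block), lost at an adjusted p = 0.888 with an estimated correlation in that fit.

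AT2G41190 stood 1.52 ± 0.19 higher in L20 before and 0.71 ± 0.19 higher after cold (limma adjusted p = 0.123 and 1.00), and was higher in L20 in both replicates at both temperatures. AT5G24240 was lower in L20 after cold in both replicates, by -1.31 and -0.81. Before cold the rule for naming required such agreement of AT2G41190. After cold both genes were picked for their small p, so the agreement is not separate evidence.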
